A study of Pseudomonas aeruginosa PAO1 with 6 samples.

How the data were processed

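Pseudomonas aeruginosa PAO1 of the UW sub-strain, wild type, was grown in nutrient broth and received 0 or 20 mM 2-oxoglutarate. Cells were harvested 30 min later, per the labels' protocols. Total RNA was copied into cDNA with random primers, fragmented, labelled with biotin and hybridised to Affymetrix GeneChips, per the same protocols. The labels give 3 arrays titled no substrate and 3 titled 2-oxoglutarate, each numbered 1 to 3. Nothing in the labels says whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

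The deposited value is the probe set intensity, a signal on a linear scale. The submitters' processing notes name MAS5, the Affymetrix method that reduces the probes of a probe set to one signal; its version, settings, scaling target and detection calls are not given in the sources used here. In the values themselves, the mean signal without the highest and lowest 2% of probe sets lay between 500.7 and 501.0 on the 6 arrays, so each array had been scaled to one level before deposit. No array was normalized further here. The table held 5896 probe sets. The 14 Affymetrix control probe sets were left out, and 5882 were tested: 5545 with a PA locus tag in the name, 199 intergenic and 138 others, such as ribosomal and transfer RNAs and genes of other strains. All values were above 0, and log2 was taken with no offset.

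Genes were named by matching the locus tag in the probe set name to NCBI's gene table for assembly ASM676v1, which held 5504 of the 5545 tags and not the other 41. In the platform's annotation 5500 probe sets had 1 gene symbol, 0 had several and 396 had no row. The sources used here name no genome build, so no coordinates are given.

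The groups were compared as labelled, 2-oxoglutarate minus no substrate, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), and p-values were adjusted by the Benjamini-Hochberg method over the 5882 probe sets. A gene was called at an adjusted p under 0.05, and counts were also taken with a fold change of at least 2. Intervals are limma's at the 95% level. For PA5530 alone an exact two-sided permutation test was run on the mean log2 signals. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 24 lists. The lists held 506 members, of which 2, fumC1 (PA4470) and hisC1 (PA4447), were not analysed here. In data simulated on 5882 genes with 3 arrays per group and 50 genes changed per fold size, the comparison recovered 28% of the genes changed 2-fold, 56% of those changed 4-fold, 86% of those changed 8-fold and 90% of those changed 16-fold, with 6 false calls. Of the changed genes with mean signal above the median, 14 of 25 were recovered at 2-fold and 20 of 22 at 4-fold. Over all signals these were 14 and 28 of 50. With the labels of 1 pair of arrays exchanged in the simulation, the comparison recovered 0 at each fold size. In a further simulation with 1 list raised, camera called that list and 0 of the others. The simulated noise was normal, independent between genes and arrays, and of a size set by the mean signal alone. Real arrays can depart from this, so the simulations may overstate recovery here.

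The lists, the limma, camera and fry tests, the alternatives described below as set beforehand and the rule for named genes were fixed before the data were examined. The permutation test of PA5530 was not among them. The rule named 12 genes of 2-oxoglutarate uptake and metabolism in any case (PA5530, mifR, mifS, rpoN, dctA, PA5167 (dctP), sucA, sucB, gltB, glnA, gdhA and aceA). With at least 5 genes past the threshold it would have named up to 12 with the largest increase and 12 with the largest decrease among those whose groups did not overlap, and with fewer, as here, the 10 with the smallest p among probe sets with a locus tag. It would also have named the 4 members of smallest p in each list past the threshold or with at least 3 members past it.

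The alternatives set beforehand were quantile normalization, centring each array on its median, an offset of 32 before log2, leaving out probe sets at or below the 0.25 quantile of mean signal, no mean-variance trend, PA locus tags only, the replicate number as a block, and each array left out in turn. Alternatives added after the signal of PA5530 on each array had been seen were leaving out 1 array of each group, in all 9 combinations, and a block for the class of ribosomal RNA signal. Array data carry no read depth, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.49 over all probe sets and 0.30 over the 2941 with a mean log2 signal above the median.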

Results

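The response of Pseudomonas aeruginosa PAO1, a Gram-negative bacterium, to 2-oxoglutarate was measured on 6 expression arrays. 2-Oxoglutarate (alpha-ketoglutarate) is a five-carbon dicarboxylate of the tricarboxylic acid cycle. Of the arrays, 3 were labelled no substrate (0 mM) and 3 were labelled 20 mM 2-oxoglutarate, all from cells taken 30 min after the addition. The median MAS5 signal per array lay between 226.6 and 305.45 over the 5882 probe sets tested. The log2 signals of any pair of arrays correlated across probe sets with r between 0.80 and 0.886. Over the 2941 probe sets of signal above the median, no substrate 1 had r of 0.898 and 0.899 with no substrate 2 and 3. With 2-oxoglutarate 2 and 3 it had 0.919 and 0.928. There 2-oxoglutarate 1 had 0.885 and 0.904 with 2-oxoglutarate 2 and 3, and 0.905 and 0.914 with no substrate 2 and 3. Over all probe sets 2-oxoglutarate 1 was not clearly nearer either group. Its r was 0.8161 and 0.8278 with 2-oxoglutarate 2 and 3, and 0.8234 and 0.8275 with no substrate 2 and 3. The array labelled no substrate 3 also had a higher r with 2-oxoglutarate 3 (0.949) than with no substrate 2 (0.935). The 9 control probe sets for yeast and Arabidopsis transcripts, which give a background level, had a median signal of 71.2, 12.9 and 9.4 on the arrays labelled no substrate 1, 2 and 3, and of 117.2, 4.6 and 26.9 on those labelled 2-oxoglutarate 1, 2 and 3.

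PA5530, which encodes a transporter of five-carbon dicarboxylates, was measured first on each array because its level bears directly on the addition of 2-oxoglutarate. On the arrays labelled no substrate 2 and 3 its signal was 327.6 and 252.2, and on those labelled 2-oxoglutarate 2 and 3 it was 3239.5 and 3486.8. The array labelled no substrate 1 had 2608.2, which was 9.07 times the geometric mean of the other arrays of its group. The array labelled 2-oxoglutarate 1 had 335, and the geometric mean of the other arrays of its group was 10.03 times that. Both arrays numbered 1 thus lay nearer the opposite group in PA5530, and in what follows every direction refers to the labels as given. By these labels the mean log2 signal was 9.23 ± 1.85 (SD, n = 3) without substrate and 10.61 ± 1.92 (SD, n = 3) with 2-oxoglutarate. The log2 fold change of 1.38 had a standard error of 0.84, a 95% interval of -0.42 to 3.17 and an adjusted p of 0.9999 by limma. An exact two-sided permutation test gave p = 0.2, and the smallest p that 3 arrays against 3 can give is 0.1. The arrays also differed in ribosomal RNA: the 16S signal was 493663 and 431840 on the arrays labelled no substrate 1 and 2 and 484298 on 2-oxoglutarate 1, against 298829 on no substrate 3 and 222223 and 294797 on 2-oxoglutarate 2 and 3. Within the 3 arrays of high 16S signal the log2 difference in PA5530 was -1.46, and within the 3 of low signal it was 3.74.

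**Figure D1:**
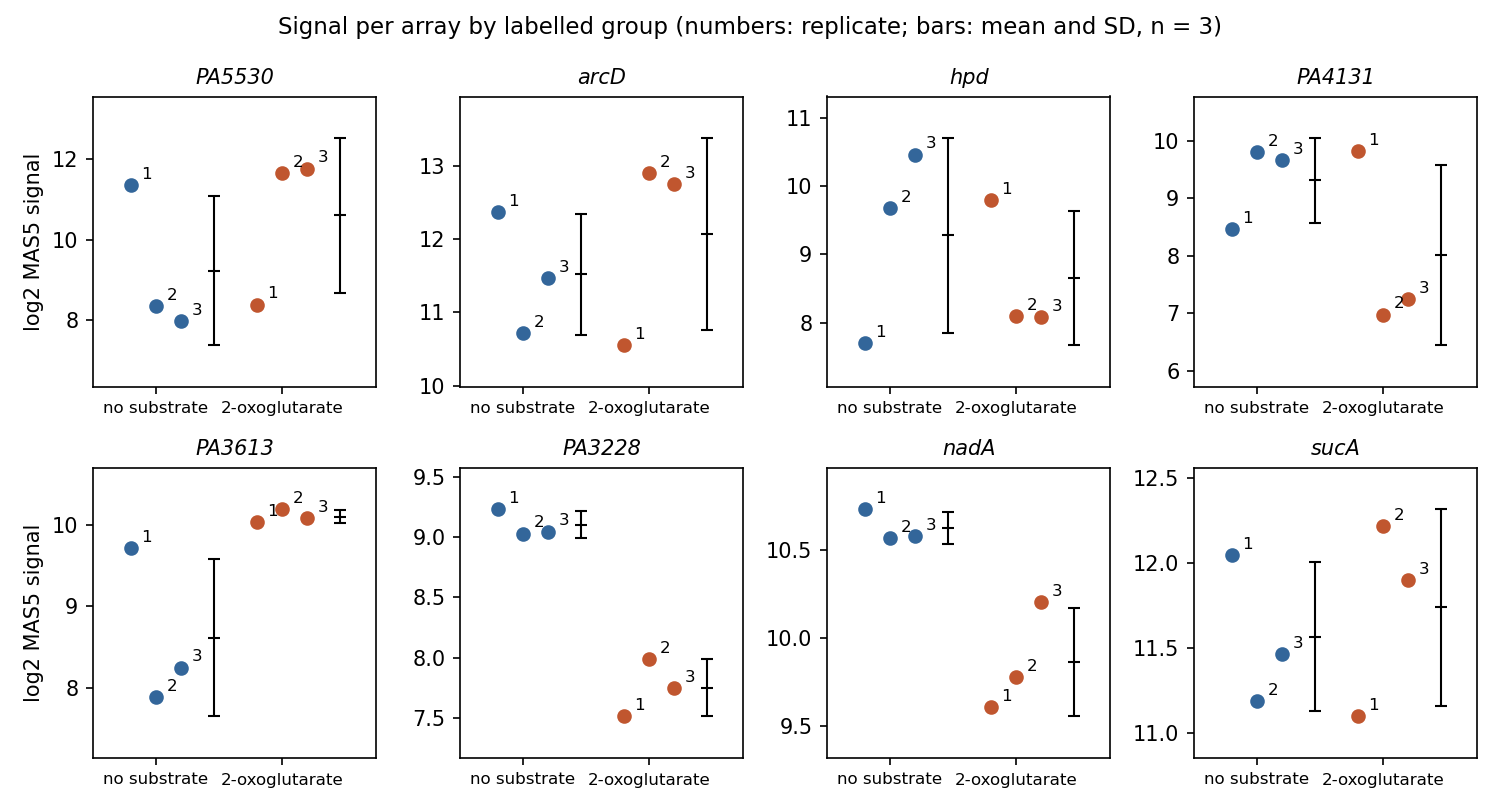
Log2 MAS5 signal of 8 genes on each array, by labelled group, with the replicate number beside each point and the group mean with its SD (n = 3) as a bar. In PA5530, arcD and sucA the array labelled no substrate 1 sits above the others of its group and 2-oxoglutarate 1 below the others of its group, in hpd and PA4131 the order is turned, and in PA3228 and nadA the labelled groups do not overlap.

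As labelled, 0 genes passed an adjusted p of 0.05 by limma, with 0 higher and 0 lower in 2-oxoglutarate, and so 0 at a fold change of at least 2. At an unadjusted p under 0.05 there were 141 probe sets, 68 higher and 73 lower, where chance alone gives 294.1. That count was 219 without the array labelled no substrate 1 and 276 without 2-oxoglutarate 1. The groups did not overlap in 452 probe sets, which is 7.68% against the 10% that chance gives for 3 against 3. The median absolute log2 fold change was 0.29, below the median standard error of 0.49. The 10 genes with the smallest p are given as not passing. Among them, phzB1 of phenazine biosynthesis had 185.4 to 215.4 on the arrays without substrate and 17.2 to 25.4 on those with 2-oxoglutarate, a log2 fold change of -3.25 ± 0.82 (SE, n = 3 per group; unadjusted p = 0.00133 by limma). All 3 lower values lay below the highest background probe set of their arrays, as did those of 185.4 and 215.4 on no substrate 1 and 2, where that probe set had 205.6 and 217.8. The probe set of phzB1 can also take up the near-identical copy phzB2. PA3228 had a log2 fold change of -1.35 ± 0.34, with signals of 522.1 to 600.7 against 182.8 to 254. Its signal of 182.8, on 2-oxoglutarate 1, lay below the highest background probe set of that array, 240.8. The quinolinate synthase gene nadA, of NAD synthesis, had -0.76 ± 0.21, and its signals of 1513.8 to 1696.3 lay above 779.8 to 1177.2. The remaining lower estimates were -3.19 for PA0118, -3.04 for PA1238 and -1.63 for PA4623, whose groups overlapped. The higher estimates were 2.35 for PA1746, 1.62 for PA3087, 1.48 for PA3613 and 1.09 for PA0201. On the lower side of the comparison, all 3 values of PA0118, PA1238 and PA1746 and 2 of the 3 of PA3087 also lay below the highest background probe set of their arrays, so the sizes of these folds are uncertain. Without the array labelled no substrate 1 the count was 1 gene, PA3613, at 2.03 with an adjusted p of 0.0194. With any other single array left out it was 0.

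**Figure D2:**
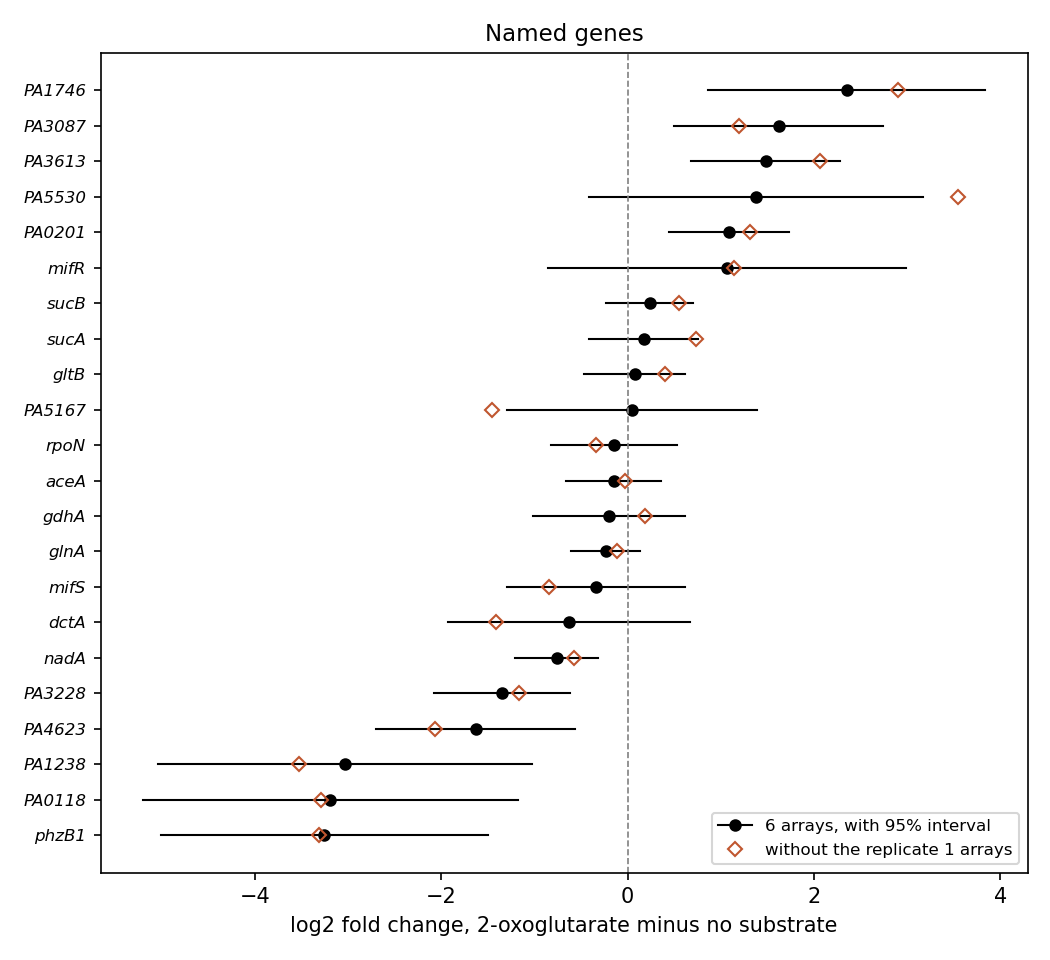
Log2 fold change of the 22 named genes, 2-oxoglutarate minus no substrate as labelled, with the 95% interval over 6 arrays (circles, lines) and the estimate without both arrays numbered 1 (diamonds). PA5530 moves from 1.38 to 3.55 and PA5167 from 0.04 to -1.46, while phzB1 stays at -3.25 and -3.31.

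The genes fixed for 2-oxoglutarate uptake and metabolism did not pass as labelled. The two-component regulator genes mifR and mifS had log2 fold changes of 1.07 ± 0.90 and -0.34 ± 0.45 (SE, n = 3 per group), and rpoN, which encodes an alternative sigma factor, had -0.15 ± 0.32. The estimate for mifR was 0.39 without no substrate 2 and 1.69 without no substrate 3, and 3 of its 6 signals (52, 18.9 and 97.4) lay below the highest background probe set of their arrays. The uptake genes dctA and PA5167 (dctP), for transport of four-carbon dicarboxylates, had -0.63 ± 0.61 and 0.04 ± 0.63. The 2-oxoglutarate dehydrogenase genes sucA and sucB had 0.17 ± 0.27 and 0.24 ± 0.22. Of the genes that join carbon and nitrogen metabolism, gltB of glutamate synthase had 0.07 ± 0.25, glnA of glutamine synthetase -0.24 ± 0.17 and gdhA of glutamate dehydrogenase -0.20 ± 0.38. The isocitrate lyase gene aceA had -0.15 ± 0.24. Each interval included 0.

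Of the 24 gene lists, 0 passed camera as labelled, 0 with an estimated correlation (smallest adjusted p = 0.978) and 0 by fry (smallest adjusted p = 0.994). The list for magnesium limitation and lipid A modification came nearest, with a median log2 fold change of 0.29 over 16 members, 11 of them above 0, and an adjusted p of 0.207 by camera. The next smallest adjusted p was 0.657. Median changes were -0.08 over 11 members of dicarboxylate uptake, 0.05 over 18 of the tricarboxylic acid cycle, -0.02 over 20 of the glyoxylate shunt and gluconeogenesis, and -0.19 over 21 of nitrogen assimilation. In 0 lists did a member pass over all probe sets. Adjusted over the list alone, 1 list had such a member, phzB1 in quorum sensing and secreted virulence factors. That list alone passed fry's test for change in either direction, at an adjusted p of 6.74e-04 over 26 members, with 10 of them above 0 and a median of -0.07. The call rested on phzB1 (adjusted p = 0.986 without it). It was lost without no substrate 1 (0.0979), without 2-oxoglutarate 1 (0.0542) and with the replicate number as a block (0.998). It was also lost with probe sets at or below the 0.25 quantile of mean signal left out (0.947). In 6 lists the median, the mean and the direction of camera differed in sign, and these medians were at most 0.10 from 0. Without the array labelled no substrate 1, camera called 1 list, magnesium limitation (adjusted p = 0.00216, and 0.833 with an estimated correlation). Without the array labelled 2-oxoglutarate 1 it called 3: magnesium limitation (0.00295), flagella, chemotaxis and type IV pili (0.00858) and ribosomal proteins (0.0388), all upward and all at an adjusted p of 0.724 with an estimated correlation.

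Because of the signal of PA5530, the comparison was also run without both arrays numbered 1, a choice made after that signal was seen. The p-values for PA5530 and for genes that go with it are therefore not independent evidence. With 2 arrays per group, 11 probe sets passed, 6 higher and 5 lower in 2-oxoglutarate, all changed at least 2-fold, and 441 had an unadjusted p under 0.05 by limma. PA5530 was 11.69 times higher (log2 fold change 3.55 ± 0.22, SE, n = 2 per group; adjusted p = 1.81e-06). Genes of the arginine deiminase pathway, by which the organism draws ATP from arginine when oxygen is short, also passed. Of these, arcD (arginine-ornithine exchange) rose by 1.73 ± 0.22, arcA (arginine deiminase) by 1.88 ± 0.30 and arcB (ornithine carbamoyltransferase) by 1.35 ± 0.23. Their adjusted p were 0.00578, 0.0221 and 0.0341. PA3613 rose by 2.06 ± 0.28 (adjusted p = 0.00829) and ddlB, a D-alanine ligase gene of cell wall synthesis, by 1.13 ± 0.20 (0.0370). PA4131 fell by 2.62 ± 0.37 (0.00829). The tyrosine catabolism gene hpd fell by 1.99 ± 0.31 and the carnitine catabolism gene dhcB by 1.74 ± 0.27, both at an adjusted p of 0.0192. Probe sets for asparagine and valine transfer RNA fell by 1.44 ± 0.26 (0.0419) and 1.17 ± 0.21 (0.0455). Apart from PA5530 and PA3613, which the rule for named genes had taken, these were named after their values were seen, and none of the 11 passed in all 6 arrays. Leaving out both arrays numbered 2 or both numbered 3 gave 0 calls, with 89 and 141 probe sets at an unadjusted p under 0.05. Over all 9 ways to leave out 1 array of each group, the next highest count was 5.

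Without the arrays numbered 1, camera called 2 of the 24 lists, both upward, and 0 with an estimated correlation (adjusted p = 0.618 for both). By fry 1 list passed in one direction, magnesium limitation (adjusted p = 0.0396). For change in either direction 3 passed, namely magnesium limitation, dicarboxylate uptake, and glucose and gluconate catabolism, each at an adjusted p of 0.0365. The dicarboxylate uptake list holds PA5530, whose signal led to leaving these arrays out, so its pass is not independent evidence. It was not tested without PA5530. In magnesium limitation and lipid A modification (adjusted p = 2.29e-06), 15 of 16 members had an estimate above 0 and the median was 0.63. Adjusted over the list alone 4 members passed, all higher. These were the regulator gene phoP (0.97 ± 0.19, SE, n = 2 per group), the outer membrane protein gene oprH (0.66 ± 0.18), and arnC (2.26 ± 0.63) and arnA (0.89 ± 0.29), which serve the addition of aminoarabinose to lipid A. The signals of arnC on the arrays labelled no substrate 2 and 3, 75.6 and 70.2, lay below their highest background probe sets, 217.8 and 101.9. In pyocin and SOS (adjusted p = 0.0283), 15 of 20 members were above 0 and 3 passed over the list alone: the R- and F-pyocin cluster genes PA0614 (0.84 ± 0.20) and PA0623 (0.82 ± 0.21), and recA (0.60 ± 0.17). In dicarboxylate uptake (camera adjusted p = 0.0863), PA5530 passed higher and the dctPQM genes PA5167 (-1.46 ± 0.28) and PA5168 (-1.21 ± 0.35) passed lower over the list alone. Over all probe sets, adjusted p was 0.0725 for PA5167 and 0.295 for PA5168. In the list of histidine, aromatic and proline catabolism (camera adjusted p = 0.0502), 6 of 14 members passed lower over the list alone. They included hpd and the genes of homogentisate breakdown maiA (-2.04 ± 0.44), fahA (-1.44 ± 0.44) and hmgA (-1.15 ± 0.33), while over all probe sets hpd alone passed. In arginine catabolism (camera adjusted p = 0.405), arcD, arcA and arcB passed and the other 12 of 15 members did not.

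**Figure D3:**
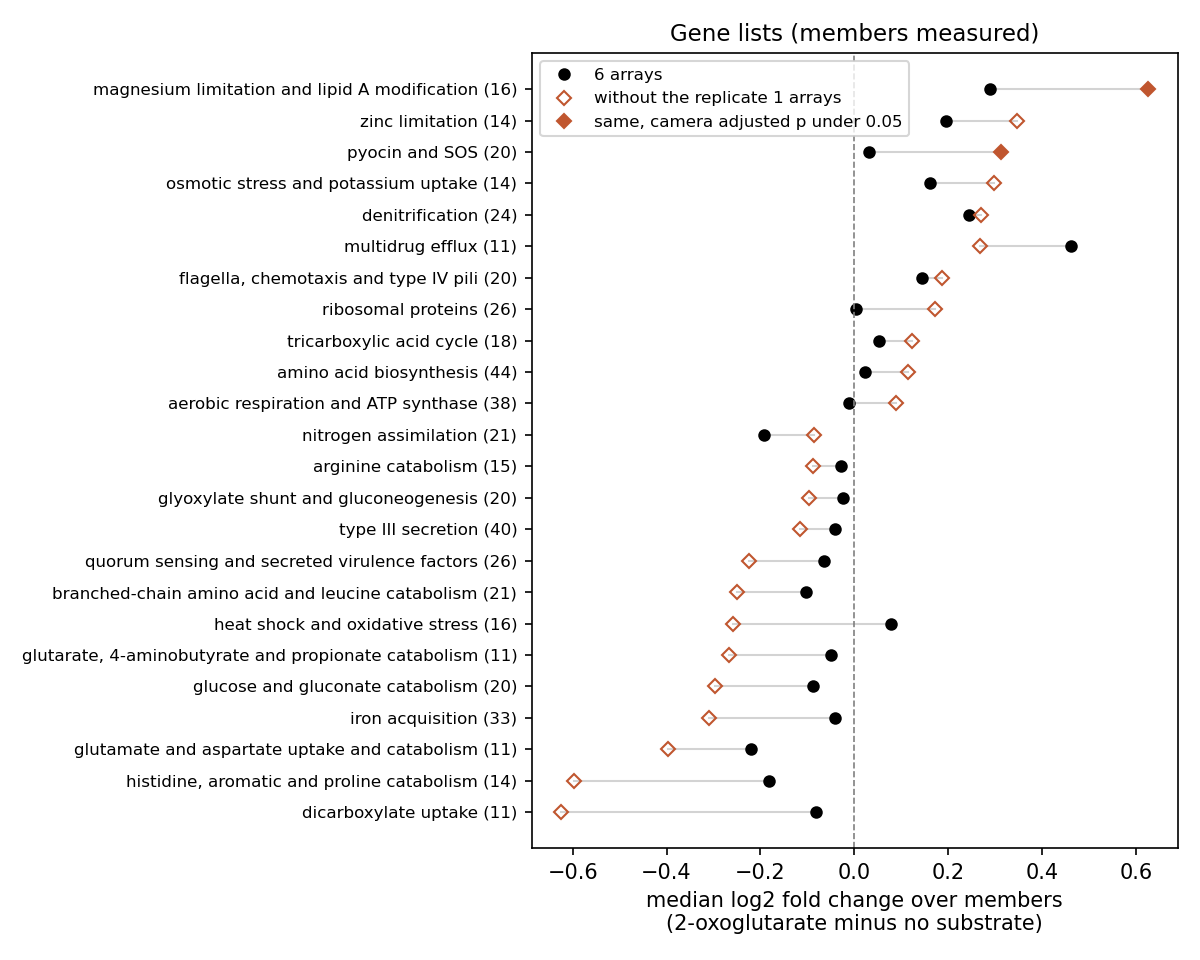
Median log2 fold change over the measured members of each of the 24 lists, 2-oxoglutarate minus no substrate as labelled, over 6 arrays (circles) and without both arrays numbered 1 (diamonds, filled where camera's adjusted p is under 0.05). The filled diamonds are magnesium limitation and lipid A modification, at 0.63, and pyocin and SOS, at 0.31, and 0 of the circles belong to a list that passed. With an estimated correlation, camera's adjusted p was 0.618 for both filled diamonds.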

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

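In this part the tests on PA5530 were chosen only after its signals had been seen. Those on the quorum sensing list follow up its pass by fry, and were chosen before their own results were seen.

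The median signal of the yeast and Arabidopsis control probe sets, which no comparison used, was 117.2 on the array labelled 2-oxoglutarate 1, above the highest of the arrays without substrate, 71.2.

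PA5530 was high on the array labelled no substrate 1 and low on the array labelled 2-oxoglutarate 1. Noise that moves many probe sets as far as PA5530 on both arrays was not seen. PA5530, a gene fixed beforehand, is itself the 1 probe set of the 2941 brighter ones (0.0340%) to lie as far. Of all 5882, 6 (0.102%) do. The cutoff was PA5530's own distance, which lesser noise would not reach, so the test cannot exclude lesser noise on these arrays. Nor does it show how far PA5530 itself varies between samples. The 2 arrays had the highest control medians of their groups (71.2 and 117.2). Their r with each other, 0.80 over all probe sets, was the lowest of any pair. The class of high ribosomal RNA signal is argued against for no substrate 1, which lay 2.98 above the other arrays of its class in log2 signal of PA5530 while those differed by 0.032, but not for 2-oxoglutarate 1, which lay 0.032 from no substrate 2 and is the 1 array with 2-oxoglutarate in that class, so that class and array cannot be told apart there. An exchange of labels or samples between the arrays numbered 1 stays open as a candidate explanation, as does an unrecorded difference between the cultures, which was not tested. Across probe sets, which are not independent, the difference of the arrays numbered 1 ran against that of the other arrays. The r was -0.285 over the brighter ones and -0.104 over all (numbers 2 and 3: -0.0466 and -0.0324, and -0.0569 and -0.0317). Of the 45 such combinations of the arrays, 2 gave larger sizes over the brighter ones, up to 0.341, and the median size was 0.0869. The 5 largest sizes, with these 2 among them, all set no substrate 1 and 2-oxoglutarate 2 and 3 against the rest. They describe the same structure, so the 2 larger sizes do not weigh against an exchange, nor do they tell it from a difference between cultures. Of the 10 genes other than PA5530 called without the arrays numbered 1, 9 changed in the opposite direction between those 2 arrays. In 6, which include arcD, arcA and arcB of the same pathway, both arrays lay nearer the opposite group. In PA4131, PA3613 and the transfer RNA probe sets for asparagine and valine, 1 of the 2 arrays stayed with its own.

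The quorum sensing list passed fry's test for change in either direction. Without phzB1, its member of smallest p, the adjusted p was 0.986. With the 17 members above the median signal it was also 0.986, but phzB1 is among the 9 dimmer members, so the tests do not separate a single probe set from low signal as the candidate source. A response of quorum sensing to 2-oxoglutarate as such was not tested apart from these.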

How the results depend on the processing

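Leaving out both arrays of one number was chosen after PA5530 had been seen, as was the block for ribosomal RNA class, while the other alternatives were planned. The 0 gene calls, the 0 lists by camera and the directions of the 22 named genes held under quantile normalization, median centring, an offset of 32, the filter on dim probe sets, no mean-variance trend, PA locus tags only and the ribosomal RNA class, except that the filter removed PA0118, PA1238, mifR and phzB1 from the test. PA5530 ranged from 1.20 to 1.43 over the planned processing alternatives, and probe sets at an unadjusted p under 0.05 from 100 to 193. Pairing by replicate number was not seen, as same-numbered deviations from the group means correlated at -0.000436, -0.0597 and 0.0370. These values cannot exclude a pairing. In genes that respond, an exchange of the arrays numbered 1 would set same-numbered deviations against each other and could mask it. With the replicate number as a block there were 0 calls, 0 lists and 114 probe sets at an unadjusted p under 0.05.

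With each array left out in turn, calls ranged from 0 to 1 (higher 0 to 1, at least 2-fold 0 to 1, at least 2-fold higher 0 to 1), lists from 0 to 3, probe sets at an unadjusted p under 0.05 from 117 to 276, and PA5530 from 0.75 to 2.49. PA5167 ranged from -0.83 to 0.66, gdhA from -0.62 to 0.17, rpoN from -0.49 to 0.055, sucA from -0.068 to 0.49 and gltB from -0.041 to 0.25, so that these 5 changed sign.

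Without both arrays numbered 1 there were 11 calls (6 higher, 5 lower; at least 2-fold 11, 6 and 5) and 2 lists. PA5530 was 3.55 and PA3613 2.06, both now past the threshold, and PA5167 (-1.46) and gdhA (0.19) changed sign. Without both numbered 2, rpoN (0.11), sucA (-0.26), sucB (-0.073) and gltB (-0.042) changed sign, and without both numbered 3, mifS (0.12) and gltB (-0.13). The cause of the changes of sign was not tested.

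The quorum sensing list's test for change in either direction lost its call without probe sets at or below the 0.25 quantile of mean signal (adjusted p = 0.947), under the block (0.998), without no substrate 1 (0.0979), without 2-oxoglutarate 1 (0.0542) and with both arrays of 1 number left out (0.0792, 0.438 and 0.976 for numbers 1 to 3). The estimates of dim genes depended on the offset: phzB1, PA0118 and PA1238 shrank to -2.13, -1.89 and -1.87 with the offset of 32, and mifR to 0.64. An offset shrinks the fold of any dim gene by arithmetic, so this cannot show whether their signal is background.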

Other observations

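The tests on gene counts over other splits of the arrays were chosen after the counts were seen, and the test on gene lists before.

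Without both arrays numbered 1, 2 members in each of 4 further lists and 1 in another passed when adjusted over the list alone, and not over all probe sets. Apart from sucA, which the rule for named genes had taken, they were named after their values were seen, and the lists did not pass. In osmotic stress and potassium uptake, betB of glycine betaine synthesis had a log2 fold change of 1.14 ± 0.21 (SE, n = 2 per group) and kdpB of the potassium pump 1.24 ± 0.35. In glutamate and aspartate uptake, PA1339 and PA1340 had -0.80 ± 0.23 and -0.78 ± 0.22. In heat shock and oxidative stress, the chaperone gene htpG had -1.25 ± 0.25 and the peroxidase gene ahpC -0.71 ± 0.21. Over all probe sets these 6 had adjusted p of 0.0560, 0.274, 0.274, 0.274, 0.0902 and 0.297 by limma. Over all 6 arrays their estimates were 0.55, 0.23, -0.26, -0.22, -0.28 and -0.40. The camera adjusted p of these 3 lists without the arrays numbered 1 was 0.0502, 0.0502 and 0.324, and 0.618 for each with an estimated correlation. In the glyoxylate shunt and gluconeogenesis, the pyruvate carboxylase genes PA5435 and PA5436 had -1.04 ± 0.29 and -1.12 ± 0.24, with adjusted p of 0.274 and 0.113 over all probe sets and estimates of -0.34 and -0.35 over all 6 arrays. In the tricarboxylic acid cycle, sucA had 0.73 ± 0.19 (adjusted p = 0.236), against 0.17 over all 6 arrays. The camera adjusted p of these lists was 0.405 and 0.0863, and 0.754 and 0.618 with an estimated correlation.

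The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. Since the labelled split gave 0 calls, 0 calls of at least 2-fold and 0 lists by camera, all 10 give as many by construction, which says nothing about chance. The highest counts of the other splits were 18 calls, 15 of at least 2-fold and 9 lists. These come from 1 split, which sets the arrays labelled no substrate 1 and 2-oxoglutarate 2 and 3 against the rest. A structure of the samples that the labels do not follow could give such a count, but it is the highest over splits examined afterwards. How high the largest count of the 10 splits runs without such a structure was not tested. Of the 18 calls, 17 are genes other than PA5530. The split along the class of ribosomal RNA signal gave 0 calls and 5 lists. Among the brighter probe sets, 17.3% separated along the split with 18 calls and 16.6% along the class of ribosomal RNA signal. Along the labels 6.43% did, where chance gives 10%. Over all probe sets the order was turned, with 940 separated along the class of ribosomal RNA signal and 807 along the split with 18 calls. Along the labels 452 were separated. Which of these splits is the stronger structure thus depended on the probe sets counted.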
